A study of Solanum lycopersicum with 12 samples.

How the data were processed

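The series comprises 12 samples of Micro-Tom tomato (Solanum lycopersicum) fruit, taken from the equatorial part of the fruit 12, 20 and 28 days after flowering. At each stage there are 2 RNA-seq input libraries and 2 libraries of RNA fragments pulled down with an antibody against N6-methyladenosine (m6A). Per the labels' protocols, RNA was extracted with Trizol, poly(A) RNA was selected and fragmented, and strand-specific libraries were made by the dUTP method and sequenced as read pairs on an Illumina NovaSeq. The 6 RNA-seq input libraries were analysed. The 6 m6A pull-down samples were not analysed here, so the comparison of m6A enrichment per gene that had been planned could not be fitted. Their labels name archives of peaks, which were not used.

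The values are FPKM (fragment numbers scaled to transcript length and library total), deposited as a table of 26657 genes by the authors. The submitters' processing notes name cutadapt, fastp, HISAT2, HOMER, StringTie and edgeR, with no version and no role for each. The genome build was not given in the sources used here. The table has 9 annotation columns ahead of the values, and their header names do not match the cells under them, so the gene ID, description and pathway were told apart by content. No coordinates were filled in. A gene's name is its description in the deposited table, and 1433 genes have none. A RefSeq gene table was searched for the same IDs and matched 0 of them, so it was not used.

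FPKM hold no counts, so the absolute depth per library is unknown and no counting interval can be given. The FPKM sum per library ran from 638829 to 666086, and 17322 to 18226 genes reached 1 FPKM. The commonest ratio of values under 0.3 FPKM placed the depth of the other 5 libraries at 0.86 to 1.14 times that of the first 12 d library. Precision followed expression level. The spread (scaled median absolute deviation) of the log2 ratio between the libraries of a stage was 0.26 to 0.3 at 1 to 2 FPKM, 0.12 to 0.14 at 4 to 8 FPKM and 0.041 to 0.048 at 64 to 128 FPKM. Pearson's r between the libraries of a stage, across genes of 1 FPKM or more on the log2(FPKM + 1) scale, was 0.992 at 12 d, 0.993 at 20 d and 0.993 at 28 d; genes are not independent replicates. Among 1401 genes of 64 FPKM or more at every stage, the squared difference between libraries fell with FPKM with a slope of -0.44 ± 0.18 (SE) on log scales, where sampling noise alone gives -1. The libraries of a stage were kept as 2 replicates, though this slope covers only high values and cannot tell differences between samples from technical ones. The series describes them as biological replicates without saying what each was drawn from, and the p-values measure only the spread between these samples, which may be technical.

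Genes with an FPKM of 1 or more in at least 2 libraries were tested (18838 genes). The 3 stages entered 1 limma fit (version 3.58.1, R 4.3.3) on log2(FPKM + 1) with a mean-variance trend, no replicate block, 3 residual degrees of freedom and 2-sided tests. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, separately for 20 d against 12 d, 28 d against 12 d and 28 d against 20 d, and a moderated F test covered all 3 stages. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values, unless given as a fold of mean FPKM. Limma was tested on simulated data for 28 d against 12 d with 18838 genes. It recovered 35 of 50 genes changed 1.25-fold (70%), 48 of 50 at 1.5-fold (96%), 50 of 50 at 2-fold (100%) and 50 of 50 at 4-fold (100%). It also called 17 of 18638 unchanged genes, a larger share of its calls than the threshold of 0.05. The simulated noise was normal, with a spread set by expression level alone. Few genes were changed in it, whereas most were called in the data.

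Before the data were examined, 29 gene lists were fixed by description and ID: m6A machinery, photosynthetic light reactions, Calvin cycle, cell division, core histones, expansins, xyloglucan endotransglucosylases, pectin modification, cellulose synthesis, aquaporins, vacuolar proton pumps, starch synthesis, starch breakdown, sucrose metabolism, ethylene synthesis and perception, ripening regulators and markers, carotenoid synthesis, auxin response, gibberellin pathway, cytokinin pathway, abscisic acid pathway, glycoalkaloid synthesis, flavonoid synthesis, cuticle formation, lignin and xylem, seed storage and maturation, heat shock proteins, pathogenesis and wounding, and cytosolic ribosomal proteins. Each was tested with camera at a preset correlation of 0.01, adjusted over the 29 lists within a comparison, and again with an estimated correlation. Camera compares a list's members with all other tested genes, so its upward and downward are relative to those genes. With an estimated correlation camera also takes its p-values at the 3 residual degrees of freedom, which keeps them high even for strong shifts. A call lost in that setting therefore cannot tell correlation among members from too few libraries. Member counts are given over all genes tested and adjusted over the list alone. A gene can belong to several lists, so their tests are not all independent. The ripening list shares Solyc09g089580.3 with the ethylene list, Solyc10g080210.2 with pectin modification, Solyc06g051800.3 with expansins and Solyc03g031860.3 with carotenoid synthesis.

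The rule for named genes was fixed at the same time. For each comparison it takes the 8 largest rises and 8 largest falls among called genes with a description other than uncharacterized, unknown or hypothetical, a mean of 10 FPKM or more in the higher stage and libraries that do not overlap between the stages. It adds the 3 called members of each list with the highest mean FPKM, or the most abundant member where none is called, and every tested member of the m6A list. The text leaves out some genes that the rule gives. A gene that the rule gives in 1 comparison may have its values given in the others. Genes named outside the rule are stated as such.

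Alternatives covered pseudocounts of 0.1 and 5, no filter and a minimum of 5 FPKM, median-ratio scaling, quantile normalization, a replicate block, a constant prior variance, fits of only the 2 stages compared, an added 2-fold threshold, an adjusted p under 0.01 for the F test, an estimated correlation for the lists, and leaving out each library in turn. Counts of genes changed 2-fold or more were followed through the alternatives only after the data were seen. KEGG pathways in the deposited table with at least 10 tested genes were tested with camera, also after the data were seen. Figures were drawn with matplotlib 3.10.9, and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.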

Results

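Poly(A) RNA of tomato fruit was profiled at 3 stages, 12, 20 and 28 days after flowering, with 2 RNA-seq libraries per stage. The series describes them as fruit expansion. At 28 d all 18 ripening regulators and markers were higher than at 12 d, so that name may not fully describe the 28 d fruit. Micro-Tom is a dwarf tomato cultivar. The series uses the 12 d fruit as the reference for a study of m6A, a methyl mark on adenosines of mRNA, during fruit expansion. Expression is given as FPKM for 26657 genes, of which 18838 were tested, and each stage value is a mean ± SD of n = 2 libraries. The first principal component of the tested genes carried 77% of the variance and the second 17.1%. FPKM summed to between 638829 and 666086 per library, and absolute depth is unknown. Across the 3 stages, 14578 genes changed by limma's moderated F test.

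The transcripts of the m6A machinery were followed first because the series is about that mark. A gene described only as an uncharacterized protein, Solyc01g104130.3, which is in the list by its ID, rose from 13.4 ± 0.362 FPKM at 12 d to 33.3 ± 0.316 at 20 d and 77.8 ± 1.92 at 28 d, 5.82-fold in all (adjusted p = 7.1e-09 by limma for 28 d against 12 d). The most abundant member, YTH domain-containing family protein 1 (Solyc01g103540.3), of the family that binds m6A, rose from 320 ± 3.6 to 403 ± 0.354 and 451 ± 1.43 FPKM. YTH domain-containing family protein 3-like (Solyc05g032850.3) rose from 19.3 ± 0.311 FPKM at 12 d to 22.7 ± 0.914 at 20 d and stood at 23.9 ± 0.823 at 28 d, where the step from 20 d passed the test only with median-ratio scaling (adjusted p = 0.026). An alkB homolog 8 (Solyc04g072390.3), related to enzymes that remove methyl groups, rose from 15.6 ± 0.156 to 25.2 ± 0.365 FPKM at 20 d. Its further step to 28.3 ± 1.81 FPKM at 28 d (log2 fold change 0.16) was called with all libraries, and the call was lost without the first 20 d library (adjusted p = 0.068), the second 20 d library (0.11) or the first 28 d library (0.14) and with a constant prior variance (0.05).

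N6-adenosine-methyltransferase MT-A70-like (Solyc08g066730.3) had 27.5 ± 1.47 FPKM at 12 d, 30.9 ± 0.167 at 20 d and 26.3 ± 0.172 at 28 d. It fell from 20 d to 28 d (log2 fold change -0.22), and its call at 20 d against 12 d (0.16) was lost without the first 12 d library (adjusted p = 0.057), without the second 20 d library (0.056) and with median-ratio scaling (0.069). Without the first 12 d library it was called lower at 28 d than at 12 d (-0.11 with adjusted p = 0.044, against -0.06 with all libraries). Methyltransferase-like protein 1 (Solyc05g056220.3) fell from 38.4 ± 0.311 FPKM at 12 d to 30.7 ± 0.953 at 28 d, and its 20 d value of 37.3 ± 0.138 did not pass the test (log2 fold change -0.04) except with median-ratio scaling (-0.1, adjusted p = 0.036). Its neighbour in ID order with a similar description, Solyc05g056210.3, rose from 29.4 ± 0.549 to 33.3 ± 0.262 FPKM at 20 d and fell to 29.7 ± 0.609 at 28 d, where the fall was not called under median-ratio scaling (adjusted p = 0.097). Reads that this pair could share were not examined, so both are uncertain. FKBP12-interacting protein of 37 kDa (Solyc03g112520.3) had 11.9 ± 1.13, 12.1 ± 0.557 and 11.1 ± 0.135 FPKM and passed no test.

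The other 4 members are described as alkB-type enzymes and had lower values. AlkB homolog 6 (Solyc01g057570.3) had 11.4 ± 0.663, 11.2 ± 0.452 and 10.3 ± 0.409 FPKM and passed no test. Solyc12g096230.2 had 4.34 ± 0.394, 5.18 ± 0.41 and 5.19 ± 0.591 FPKM; it was not called with all libraries, but was called higher at 28 d than at 12 d without the second 28 d library (log2 fold change 0.31) and with quantile normalization (0.36). Solyc09g074920.3 had 3.66 ± 0.128, 3.58 ± 0.403 and 3.98 ± 0.362 FPKM and was called higher at 28 d only with quantile normalization (log2 fold change 0.27 against 12 d and 0.29 against 20 d). DNA oxidative demethylase ALKBH2 (Solyc04g015080.3) fell from 3.38 ± 0.018 FPKM at 12 d to 2.72 ± 0.125 at 28 d (log2 fold change -0.24, adjusted p = 0.019), a call lost without the first (adjusted p = 0.057) or second 12 d library (0.063), without the second 28 d library (0.097) and with quantile normalization (0.7). Its value at 28 d against 20 d was called lower only with a constant prior variance (-0.17, adjusted p = 0.021). As a group, 6 of 12 tested members rose and 0 fell at 20 d against 12 d, and the list did not pass camera (median log2 fold change 0.17, adjusted p = 0.087). With median-ratio scaling 5 rose and 1 fell. At 28 d against 12 d, 4 rose and 2 fell (median 0.05, adjusted p = 0.28), and at 28 d against 20 d, 3 rose and 3 fell (median -0.05, mean 0.06, adjusted p = 0.48). The last median changed sign with median-ratio scaling (0.02, 4 higher and 2 lower) and quantile normalization (0.06, 4 and 3). Quantile normalization gave 6 higher and 1 lower at 28 d against 12 d. Adjusted over the list alone, the member counts were the same.

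**Figure D1:**
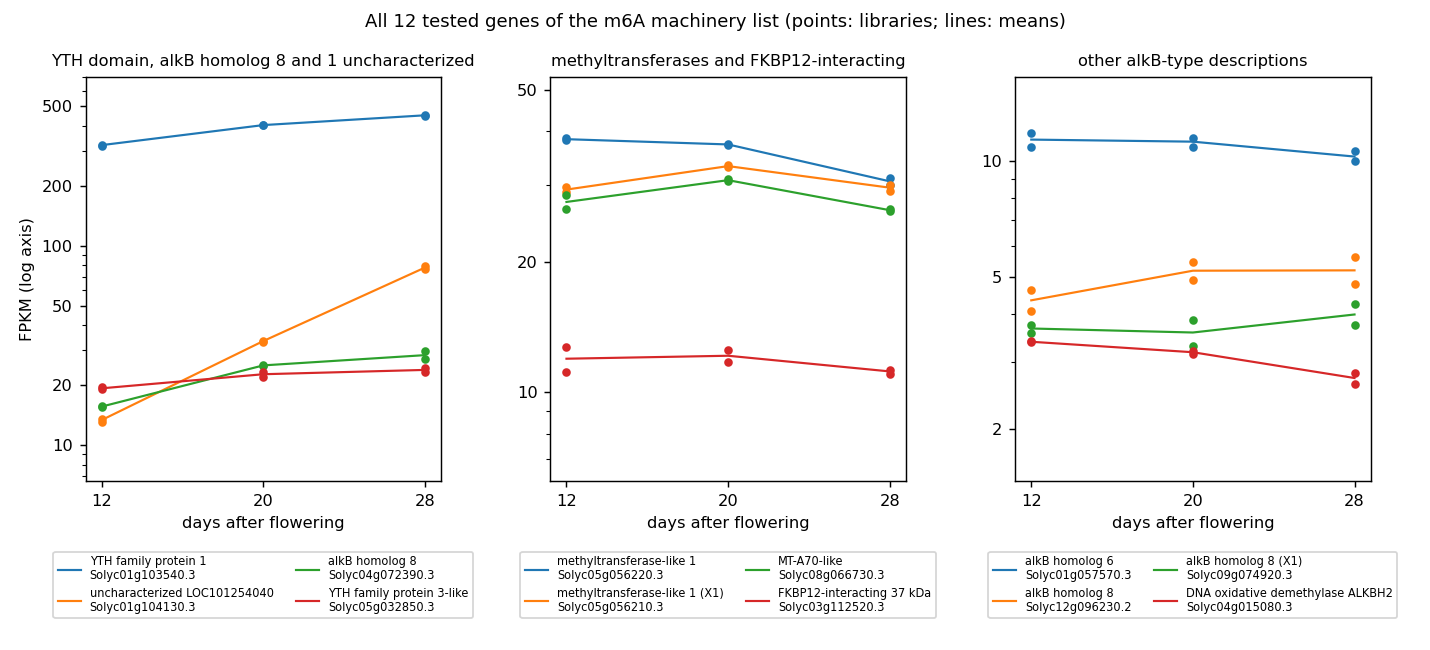
FPKM (log axis, a different range in each panel) of the 12 tested genes of the m6A machinery list against days after flowering; points are libraries and lines join stage means of n = 2. Solyc01g104130.3 runs from 13.4 to 77.8 FPKM, while the methyltransferase-like genes stay between 26.3 and 38.4 FPKM.

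At 20 d compared with 12 d, transcripts of photosynthesis, carbon fixation and nucleosome assembly were lower and seed storage transcripts were higher. Photosystem II 10 kDa polypeptide (Solyc07g066310.3) fell from 1315 ± 16.7 to 655 ± 6.53 FPKM, and chlorophyll a-b binding protein 3A (Solyc03g005760.1), which harvests light, fell from 729 ± 15.1 to 333 ± 9.88 FPKM. Ribulose bisphosphate carboxylase small chain 1 (Solyc02g063150.3), of the enzyme that fixes carbon dioxide, fell 6.53-fold from 392 ± 5.15 to 60 ± 1.4 FPKM. Histone H2A-like (Solyc09g010400.3) fell from 193 ± 1.11 to 140 ± 0.588 FPKM. Vicilin (Solyc09g082340.2), a storage protein of seeds, rose 9.65-fold from 94 ± 1.67 to 907 ± 9.01 FPKM, and 2S sulfur-rich seed storage protein 2-like (Solyc08g080490.3) rose 5.63-fold from 310 ± 6.84 to 1747 ± 8.38 FPKM.

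In total 11486 genes (61%) were called at 20 d, 6415 higher and 5071 lower. With median-ratio scaling the split was 5274 higher and 5903 lower. Changes of 2-fold or more were fewer, 504 higher and 872 lower. Among the largest changes, a defensin-like protein (Solyc07g006380.3), of a family of small antimicrobial proteins, fell 773-fold from 3891 ± 14.7 to 5.04 ± 0.43 FPKM, and a metallocarboxypeptidase inhibitor (Solyc07g007250.3) fell 187-fold from 815 ± 5.14 to 4.35 ± 0.00645 FPKM. Its neighbour Solyc07g007260.3, with a similar description, fell from 186 ± 2.59 to 0.307 ± 0.158 FPKM, and sharing of reads between them was not examined. Cysteine protease inhibitor 10-like (Solyc03g098700.1) fell from 179 ± 8.22 to 2.49 ± 0.86 FPKM, and ribonuclease MC-like (Solyc07g006560.3) from 44.8 ± 1.05 to 0.692 ± 0.0622 FPKM. Polygalacturonase-2 (Solyc10g080210.2), which degrades pectin during ripening, rose from 0.437 ± 0.121 to 37.4 ± 1.27 FPKM. Mannan endo-1,4-beta-mannosidase 4 (Solyc01g008710.4) was listed at 0 in both 12 d libraries and at 12.4 and 13.3 FPKM at 20 d. Protein LE25 (Solyc10g078770.2) rose 18.3-fold to 61 ± 3.8 FPKM, and stood at 4.61 ± 0.371 FPKM at 28 d. A pair of lipid-transfer proteins next to each other in ID order rose 11.4-fold (Solyc01g090360.3) and 11-fold (Solyc01g090350.3), with the same uncertainty about shared reads. The largest fitted rise, of glucan endo-1,3-beta-glucosidase B (Solyc01g059980.3, 0.0354 ± 0.00911 to 138 ± 4.71 FPKM, adjusted p = 0.016), had a log2 fold change of 7.07 with an SE of 1.9. The 28 d libraries in the same fit stood at 0.0293 and 126 FPKM. Without the first or second 28 d library the adjusted p was 8.9e-08 and 2.7e-07, and it was 1e-07 with only the 2 stages compared. Leaving out any of the 4 libraries compared kept the log2 fold change between 7.03 and 7.1 but lost the call. The adjusted p was then 0.067 without either 12 d library, 0.064 without the first 20 d library and 0.066 without the second. A neighbour of the same description (Solyc01g059965.1), chosen after its values were seen, went from 30.3 and 30.4 FPKM at 12 d to 11.8 and 12.6 at 20 d, so the rise is uncertain.

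Of the 29 lists, 17 passed camera at 20 d against 12 d, 5 upward and 12 downward, and 4 of them held with an estimated correlation. The photosynthetic light reactions had 64 of 74 members lower and 2 higher (median log2 fold change -1.55, adjusted p = 1.5e-24, and adjusted p = 0.023 with an estimated correlation). In the Calvin cycle 17 of 18 fell and 0 rose (median -1.38, adjusted p = 1.2e-11, and adjusted p = 0.042 with an estimated correlation). Of the core histones 26 of 30 fell and 1 rose (median -0.85, adjusted p = 2.5e-09, and adjusted p = 0.042 with an estimated correlation). In the seed storage and maturation list, which includes storage proteins of seeds, another tissue of the fruit, 35 of 41 rose and 1 fell (median 1.64, adjusted p = 1.5e-10, and adjusted p = 0.042 with an estimated correlation). This rise was measured in the same libraries as every other list described for 20 d. Dehydrins are in the list too. Dehydrin Solyc04g082200.2 had 1747 ± 43.6, 2599 ± 129 and 2724 ± 127 FPKM at the 3 stages, while 33 of the 41 members fell from 20 d to 28 d.

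The remaining downward lists lost their call with an estimated correlation. Expansins, which loosen cell walls, had 12 of 16 lower and 2 higher (adjusted p = 0.0013, and adjusted p = 0.12 with an estimated correlation). One expansin (Solyc02g088100.3) fell 3.14-fold from 168 ± 2.41 FPKM and another (Solyc06g051800.3) rose 5.52-fold from 5.11 ± 1.12 FPKM. Pectin modification had 42 of 77 lower and 17 higher (adjusted p = 0.0013, and adjusted p = 0.11 with an estimated correlation). All 5 glycoalkaloid synthesis genes fell (adjusted p = 0.0013, and adjusted p = 0.2 with an estimated correlation), among them 2-oxoglutarate-dependent dioxygenase 2 (Solyc07g043420.3), 2.56-fold from 190 ± 1.21 FPKM. Cuticle formation had 32 of 53 lower and 15 higher (adjusted p = 0.0013, and adjusted p = 0.11 with an estimated correlation). Cellulose synthesis had 11 of 23 lower and 3 higher (adjusted p = 0.025, and adjusted p = 0.31 with an estimated correlation). Cellulose synthase A catalytic subunit 1 (Solyc08g061100.3) fell from 239 ± 1.93 to 208 ± 0.403 FPKM, a call lost with quantile normalization (adjusted p = 0.18). Vacuolar proton pumps had 15 of 29 lower and 5 higher (adjusted p = 0.028, and adjusted p = 0.14 with an estimated correlation). Their subunit G 1-like (Solyc04g049330.3) fell 1.67-fold, and subunit B 2 (Solyc01g111760.3) rose from 204 ± 0.271 to 221 ± 1.53 FPKM, a call lost with median-ratio scaling (adjusted p = 0.059). Cytosolic ribosomal proteins had 131 of 204 lower and 22 higher (median -0.16, adjusted p = 3.8e-10, and adjusted p = 0.12 with an estimated correlation). With quantile normalization 91 were lower and 51 higher (median -0.06), and with median-ratio scaling 148 and 14. Lignin and xylem had 28 of 50 lower and 16 higher (adjusted p = 0.03, and adjusted p = 0.14 with an estimated correlation), and pathogenesis and wounding had 33 of 68 lower and 18 higher (adjusted p = 0.031, and adjusted p = 0.15 with an estimated correlation). Median-ratio scaling ended both of these calls (adjusted p = 0.085 and 0.092). Class I chitinase (Solyc10g017970.1), a defence enzyme, rose 3.52-fold to 8127 ± 263 FPKM within the latter list.

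Besides the seed list, 4 lists passed upward. Ethylene synthesis and perception had 24 of 37 higher and 8 lower (adjusted p = 0.0077, and adjusted p = 0.12 with an estimated correlation). Ripening regulators and markers had 12 of 18 higher and 3 lower (adjusted p = 0.0044, and adjusted p = 0.12 with an estimated correlation). Auxin response had 30 of 63 higher and 10 lower (adjusted p = 0.03, and adjusted p = 0.14 with an estimated correlation), and heat shock proteins had 20 of 36 higher and 6 lower (adjusted p = 0.03, and adjusted p = 0.14 with an estimated correlation). 1-aminocyclopropane-1-carboxylate oxidase 1 (Solyc07g049530.3), which makes ethylene, rose 2.2-fold from 294 ± 0.566 FPKM. Agamous-like MADS-box protein AGL8 homolog (Solyc03g114830.3) rose from 208 ± 4.8 to 228 ± 4.59 FPKM, a call lost without the first 12 d (adjusted p = 0.059) or first 20 d library (0.055), with median-ratio scaling (0.092) and with a constant prior variance (0.051). The lists that did not pass at 20 d, besides the m6A machinery, were cell division (9 higher, 10 lower of 41), xyloglucan endotransglucosylases (4 and 6 of 16), and aquaporins (6 and 10 of 28). Neither did starch synthesis (3 and 8 of 15), starch breakdown (6 and 10 of 19), sucrose metabolism (7 and 11 of 25) or carotenoid synthesis (4 and 9 of 19). The hormone and flavonoid lists that did not pass were gibberellin (12 and 10 of 28), cytokinin (11 and 9 of 28), abscisic acid (10 and 4 of 24) and flavonoid synthesis (3 and 6 of 13). Their adjusted p ran from 0.072 to 0.85. Flavonoid synthesis, at 0.072, passed downward without the second 20 d library (adjusted p = 0.0487) and with a pseudocount of 0.1 (0.0465), with adjusted p = 0.32 as deposited with an estimated correlation. Median-ratio scaling gave 3 higher and 16 lower for vacuolar proton pumps and 1 and 7 for flavonoid synthesis, and quantile normalization gave 9 and 9 for cell division. Adjusted over the list alone, the counts of higher and lower members became 8 and 8 for cell division, 5 and 16 for vacuolar proton pumps, 25 and 8 for ethylene, 16 and 32 for cuticle formation, 18 and 35 for pathogenesis and 22 and 133 for ribosomal proteins, and were the same for the other lists.

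At 28 d compared with 12 d, ripening-related transcripts were higher and photosynthesis transcripts lower. Both lists passed camera at the preset correlation (adjusted p = 1.8e-12 for ripening and 9.1e-14 for the light reactions), and neither passed with an estimated correlation (adjusted p = 0.055 for each). Polygalacturonase-2 (Solyc10g080210.2) rose from 0.437 ± 0.121 to 1536 ± 10.2 FPKM, a 1-aminocyclopropane-1-carboxylate oxidase homolog (Solyc09g089580.3) rose 15.9-fold from 174 ± 1.6 to 2758 ± 102 FPKM, and phytoene synthase 1 (Solyc03g031860.3), the entry enzyme of carotenoid synthesis, rose 9.55-fold from 33.1 ± 0.757 to 317 ± 0.16 FPKM. Ribulose bisphosphate carboxylase small chain 1 (Solyc02g063150.3) fell 17.7-fold to 22.1 ± 0.256 FPKM, and photosystem II 10 kDa polypeptide (Solyc07g066310.3) fell 2.64-fold to 498 ± 8.28 FPKM. Sucrose synthase (Solyc12g009300.3), which cleaves sucrose, fell 15.7-fold from 551 ± 1.65 to 35.1 ± 1.01 FPKM, whereas acid beta-fructofuranosidase (Solyc03g083910.4), an invertase, rose 4.67-fold from 54.8 ± 0.477 to 256 ± 5.87 FPKM.

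**Figure D2:**
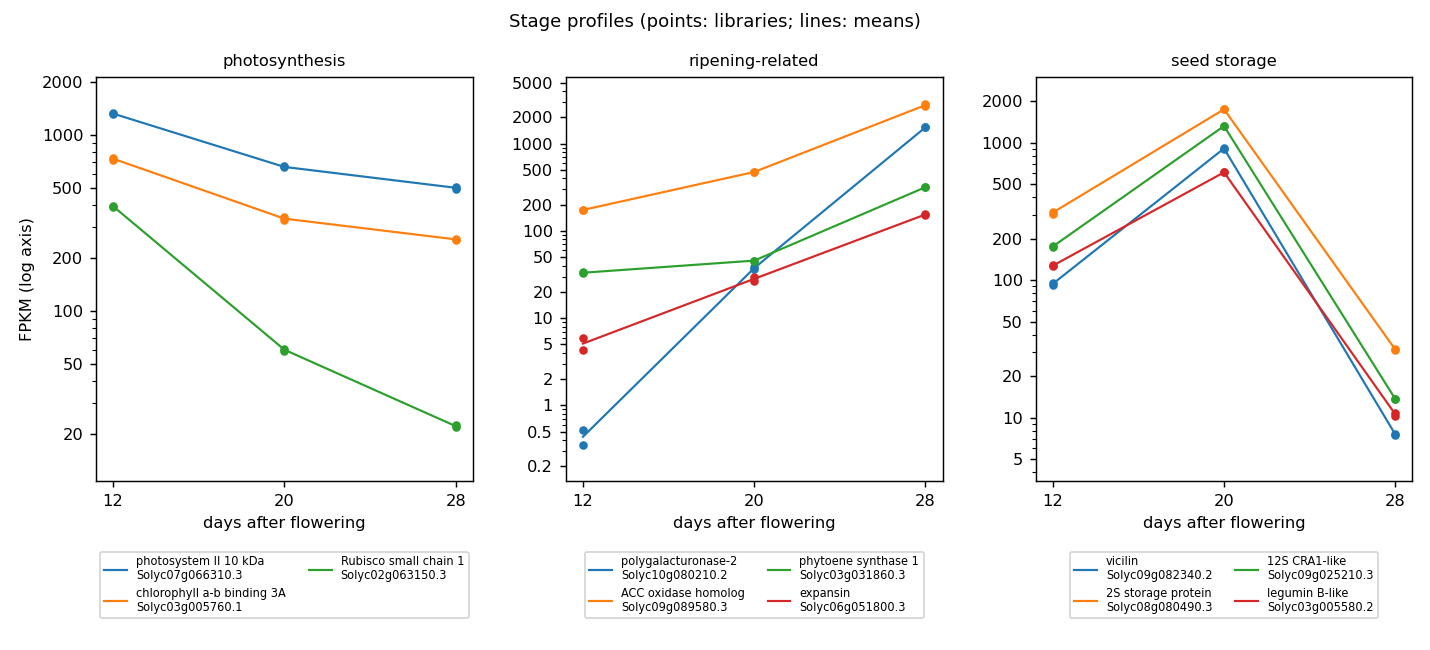
FPKM (log axis, a different range in each panel) of photosynthesis, ripening-related and seed storage genes against days after flowering; points are libraries and lines join stage means of n = 2. Polygalacturonase-2 runs from 0.437 to 1536 FPKM, and vicilin from 94 to 907 and then 7.55 FPKM.

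In total 13361 genes (70.9%) were called at 28 d against 12 d, 5897 higher and 7464 lower. With quantile normalization the split turned to 7319 higher and 6066 lower, and the median log2 fold change of all tested genes moved from -0.051 to 0.056. Of the calls, 941 were 2-fold or more higher and 1875 were 2-fold or more lower. Mannan endo-1,4-beta-mannosidase 4 (Solyc01g008710.4), listed at 0 in both 12 d libraries, stood at 708 and 719 FPKM at 28 d. A 2-oxoglutarate/Fe(II)-dependent dioxygenase-like protein (Solyc03g095900.3) rose from 0.587 ± 0.0396 to 332 ± 5.37 FPKM, branched-chain-amino-acid aminotransferase 2 (Solyc12g088220.2) from 0.24 ± 0.0737 to 87.4 ± 2.23 FPKM and a 2-alkenal reductase-like gene (Solyc07g045090.3) from 0.0431 ± 0.0272 to 71.4 ± 0.457 FPKM. A putative cell wall protein (Solyc07g054310.2) fell from 978 ± 3.44 to 1.25 ± 0.283 FPKM and a GDSL esterase/lipase (Solyc11g006250.2) fell 77.7-fold from 1155 ± 7.02 to 14.9 ± 0.609 FPKM. Putative lipid-transfer protein DIR1 (Solyc07g065110.1) fell from 199 ± 4.14 to 0.29 ± 0.0584 FPKM, and 36.4 kDa proline-rich protein (Solyc07g043000.3) from 103 ± 3.79 to 0.273 ± 0.0384 FPKM. The defensin-like gene Solyc07g006380.3, at 3880 and 3901 FPKM at 12 d, was listed at 0 in both 28 d libraries. A listing at 0 is not read as absence here, since probable polyribonucleotide nucleotidyltransferase 1 (Solyc08g066120.3), at 21.3 FPKM in a 12 d library, is at 0 in the other.

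At 28 d against 12 d, 14 lists passed camera, 3 upward and 11 downward, and 0 held with an estimated correlation. That setting also has only 3 residual degrees of freedom, which keeps its p-values high. All 18 ripening regulators and markers rose, 15 of them 2-fold or more (median log2 fold change 2.76, adjusted p = 1.8e-12, and adjusted p = 0.055 with an estimated correlation). Ethylene synthesis and perception had 29 of 37 higher and 5 lower (adjusted p = 8.2e-07, and adjusted p = 0.055 with an estimated correlation). Heat shock proteins had 26 of 36 higher and 6 lower (median 1.25, adjusted p = 1.5e-06, and adjusted p = 0.055 with an estimated correlation), including a chloroplastic small heat shock protein (Solyc03g082420.3) at 0.51 ± 0.071 FPKM at 12 d and 61.7 ± 0.392 at 28 d. The photosynthetic light reactions had 62 of 74 lower and 5 higher (median -2.05, adjusted p = 9.1e-14, and adjusted p = 0.055 with an estimated correlation), and the Calvin cycle 16 of 18 lower and 0 higher (adjusted p = 1.3e-07, and adjusted p = 0.055 with an estimated correlation). Core histones had 22 of 30 lower and 5 higher (adjusted p = 0.00052, and adjusted p = 0.095 with an estimated correlation). Seed storage and maturation had 29 of 41 lower and 5 higher (median -1.16, adjusted p = 7.5e-05, and adjusted p = 0.072 with an estimated correlation), a fall measured in the same libraries as the lists just given.

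Expansins had 13 of 16 lower and 2 higher (adjusted p = 0.006, and adjusted p = 0.13 with an estimated correlation), and the expansin Solyc06g051800.3 rose 30.2-fold to 154 ± 2.03 FPKM. Cellulose synthesis had 16 of 23 lower and 5 higher (adjusted p = 0.034, and adjusted p = 0.37 with an estimated correlation). All 5 glycoalkaloid genes fell (adjusted p = 0.006, and adjusted p = 0.29 with an estimated correlation). Flavonoid synthesis had 10 of 13 lower and 2 higher (adjusted p = 0.019, and adjusted p = 0.29 with an estimated correlation), with chalcone synthase 2 (Solyc05g053550.3) lower 2.24-fold. Cuticle formation had 35 of 53 lower and 15 higher (adjusted p = 0.0066, and adjusted p = 0.11 with an estimated correlation). Non-specific lipid-transfer protein 2-like (Solyc10g075070.2) fell 2.1-fold from 2020 ± 37.5 FPKM. Pathogenesis and wounding had 44 of 68 lower and 17 higher (adjusted p = 0.018, and adjusted p = 0.15 with an estimated correlation), and cytosolic ribosomal proteins had 162 of 204 lower and 11 higher (median -0.34, adjusted p = 5e-12, and adjusted p = 0.11 with an estimated correlation). The lists that did not pass at 28 d against 12 d, besides the m6A machinery, were cell division (5 higher, 24 lower of 41), xyloglucan endotransglucosylases (4 and 9 of 16), pectin modification (18 and 43 of 77) and aquaporins (7 and 15 of 28). Neither did vacuolar proton pumps (9 and 13 of 29), starch synthesis (3 and 8 of 15), starch breakdown (6 and 11 of 19), sucrose metabolism (7 and 14 of 25) or carotenoid synthesis (7 and 7 of 19). The others that did not pass were auxin response (21 and 25 of 63), gibberellin (12 and 13 of 28), cytokinin (8 and 14 of 28), abscisic acid (9 and 9 of 24) and lignin and xylem (19 and 27 of 50). The adjusted p of these lists ran from 0.051 to 0.97. Cell division, at 0.051, passed downward with median-ratio scaling (adjusted p = 0.0497) and without the second 28 d library (0.0472), with adjusted p = 0.29 as deposited with an estimated correlation. Gibberellin 2-oxidase 2 (Solyc07g056670.3), which inactivates gibberellins, rose 10.9-fold from 28.8 ± 0.407 to 314 ± 4.23 FPKM. Over all tested genes the median log2 fold change at 28 d against 12 d was -0.051, and camera's direction is relative to the other genes. Camera pointed upward while the median was negative for carotenoid synthesis (median -0.04, mean 0.1), gibberellin (median -0.17, mean -0.08) and abscisic acid (median -0.03). These medians and that of the vacuolar proton pumps (-0.04) changed sign with quantile normalization (0.1, 0.14, 0.01 and 0.04). The split of auxin response turned to 25 higher and 23 lower with median-ratio scaling and to 29 and 20 with quantile normalization. Quantile normalization also gave 12 higher and 11 lower for vacuolar proton pumps, 12 and 10 for gibberellin, 7 and 6 for carotenoid synthesis and 11 and 6 for abscisic acid. Median-ratio scaling gave 10 and 9 for abscisic acid. Among lists that passed, quantile normalization raised the higher members to 11 for the light reactions, 8 for seed storage and 24 for ribosomal proteins, with 61, 25 and 134 lower. The Calvin cycle had 1 higher member with either scaling. Adjusted over the list alone, the counts of higher and lower members became 1 and 17 for the Calvin cycle, 7 and 8 for carotenoid synthesis, 24 and 25 for auxin response and 18 and 44 for pathogenesis, and were the same for the other lists.

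At 28 d compared with 20 d, seed storage transcripts fell while ripening-related and heat shock transcripts rose. Vicilin (Solyc09g082340.2) fell 120-fold from 907 ± 9.01 to 7.55 ± 0.0274 FPKM, 12S seed storage protein CRA1-like (Solyc09g025210.3) fell 96.6-fold from 1320 ± 10.8 to 13.7 ± 0.0224 FPKM, and oleosin 5-like (Solyc12g010920.2), a coat protein of seed oil bodies, fell 73.1-fold to 1.48 ± 0.315 FPKM. Polygalacturonase-2 (Solyc10g080210.2) rose 41.1-fold from 37.4 ± 1.27 to 1536 ± 10.2 FPKM, phytoene synthase 1 (Solyc03g031860.3) rose 6.94-fold and histidine decarboxylase (Solyc08g066240.3) rose from 0.0828 ± 0.0156 to 61.7 ± 1.34 FPKM. 15-cis-zeta-carotene isomerase (Solyc12g098710.2), of carotenoid synthesis, rose 3.05-fold from 22.2 ± 0.562 to 67.6 ± 1.93 FPKM.

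In total 9976 genes (53%) were called, 3106 higher and 6870 lower. The split moved to 4340 higher and 5024 lower with median-ratio scaling and to 4063 higher and 4661 lower with quantile normalization. Changes of 2-fold or more numbered 373 higher and 574 lower. With a pseudocount of 5 they numbered 216 higher and 183 lower, and with 0.1 they numbered 479 and 1194. With quantile normalization they numbered 452 higher and 409 lower. DETOXIFICATION 27-like (Solyc04g074840.3) was listed at 0.0194 and 0 FPKM at 20 d and at 50.1 and 49.5 at 28 d. Receptor-like protein kinase THESEUS 1 (Solyc07g063475.1) was listed at 8.78 and 0 FPKM at 12 d, at 0 in both 20 d libraries and at 28.9 and 30.2 at 28 d. A neighbour of the same description (Solyc07g063480.3), chosen after its values were seen, had 13.8 and 13.1 at 20 d and 0.0515 and 0.0811 at 28 d, so the rise is uncertain. Ribonuclease MC-like (Solyc07g006560.3) fell from 0.692 ± 0.0622 to 0.273 ± 0.0416 FPKM, a change of -0.41 that became 0.025 with quantile normalization. A 1-aminocyclopropane-1-carboxylate oxidase (Solyc02g036350.3) rose from 1849 ± 4 to 2150 ± 0.483 FPKM (0.22), a difference that quantile normalization set to 0, since the gene held the same rank in these 4 libraries.

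Of the lists, 11 passed camera at 28 d against 20 d, 5 upward and 6 downward, and 5 held with an estimated correlation. All 18 ripening regulators and markers rose (median log2 fold change 2.3, adjusted p = 6.3e-22, and adjusted p = 0.042 with an estimated correlation). Heat shock proteins had 24 of 36 higher and 5 lower (median 1.14, adjusted p = 1.5e-10, and adjusted p = 0.042 with an estimated correlation). Heat shock cognate 70 kDa protein 2-like (Solyc09g010630.3), the most abundant of those named, fell from 1657 ± 10.5 to 1353 ± 9.26 FPKM. Ethylene synthesis and perception had 23 of 37 higher and 6 lower (median 0.33, adjusted p = 1.1e-08, and adjusted p = 0.043 with an estimated correlation). In seed storage and maturation 33 of 41 fell and 0 rose (median -2.39, adjusted p = 1.9e-12, and adjusted p = 0.042 with an estimated correlation), in the same libraries as the other lists. With either scaling 1 member rose and 32 fell. The photosynthetic light reactions had 54 of 74 lower and 8 higher (median -0.45, adjusted p = 6e-06, and adjusted p = 0.045 with an estimated correlation), and with quantile normalization 47 lower and 13 higher.

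Carotenoid synthesis had 10 of 19 higher and 4 lower (adjusted p = 0.0015, and adjusted p = 0.31 with an estimated correlation). Its member zeaxanthin epoxidase (Solyc02g090890.3) rose from 46 ± 0.359 to 48.7 ± 0.402 FPKM (0.08), a call that was lost without any one of the 6 libraries (adjusted p from 0.052 to 0.14). It was also lost with a replicate block (adjusted p = 0.051), a constant prior variance (0.11) and only the 2 stages compared (0.054). Vacuolar proton pumps had 13 of 29 higher and 1 lower (median 0.07, adjusted p = 4.5e-05, and adjusted p = 0.075 with an estimated correlation), and 0 lower with either scaling. The Calvin cycle had 14 of 18 lower and 2 higher (adjusted p = 0.00071, and adjusted p = 0.11 with an estimated correlation), and cell division 28 of 41 lower and 0 higher (adjusted p = 0.018, and adjusted p = 0.27 with an estimated correlation). The cell division counts became 21 lower and 3 higher with median-ratio scaling (median -0.21) and 12 lower and 4 higher with quantile normalization (-0.13), against a median of -0.28 as deposited. Cyclin-D1-1 (Solyc05g006050.3), which drives entry into the cell cycle, fell from 32.1 ± 1.45 to 18.8 ± 0.554 FPKM. Replication licensing factor MCM2 (Solyc11g040120.2) fell from 32.6 ± 1.25 to 29.5 ± 0.827 FPKM, a call lost without the second 20 d library (adjusted p = 0.1), without the first 28 d library (0.12) and with median-ratio scaling (0.27). Pathogenesis and wounding had 39 of 68 lower and 11 higher (adjusted p = 0.022, and adjusted p = 0.19 with an estimated correlation), with pathogenesis-related protein P2 (Solyc01g097240.3) lower 2.18-fold. Cytosolic ribosomal proteins had 155 of 204 lower and 4 higher (adjusted p = 9e-10, and adjusted p = 0.16 with an estimated correlation), and with median-ratio scaling 111 lower and 12 higher.

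The lists that did not pass at 28 d against 20 d, besides the m6A machinery, were core histones (10 higher, 11 lower of 30), expansins (3 and 11 of 16), xyloglucan endotransglucosylases (3 and 9 of 16), pectin modification (19 and 35 of 77) and cellulose synthesis (5 and 15 of 23). Aquaporins (7 and 12 of 28), starch synthesis (4 and 5 of 15), starch breakdown (6 and 8 of 19) and sucrose metabolism (6 and 12 of 25) did not pass. Of the hormone lists, auxin response (12 and 28 of 63), gibberellin (7 and 11 of 28), cytokinin (3 and 14 of 28) and abscisic acid (5 and 12 of 24) did not pass. The remaining lists that did not pass were glycoalkaloid synthesis (0 and 4 of 5), flavonoid synthesis (2 and 10 of 13), cuticle formation (14 and 27 of 53) and lignin and xylem (15 and 22 of 50). Adjusted p over these lists ran from 0.064 to 0.97. With median-ratio scaling, expansins (adjusted p = 0.03), cellulose synthesis (0.024), cytokinin (0.03), glycoalkaloid synthesis (0.032) and flavonoid synthesis (0.02) passed downward. Without the second 20 d library, cellulose synthesis (adjusted p = 0.0438) and glycoalkaloid synthesis (0.0187) did so too. As deposited and with an estimated correlation, adjusted p = 0.33 for expansins, 0.48 for cellulose synthesis, 0.27 for cytokinin, 0.48 for glycoalkaloid synthesis and 0.39 for flavonoid synthesis. A histone H2A variant (Solyc09g065755.1) fell from 166 ± 3.19 to 157 ± 0.644 FPKM (-0.08), which median-ratio scaling turned to 0.0093; the call was also lost without the first 20 d library (adjusted p = 0.093), without the first (0.07) or second 28 d library (0.092) and with a constant prior variance (0.12). Several of these splits moved with the scaling. Gibberellin turned to 7 higher and 6 lower with median-ratio scaling and 7 and 5 with quantile normalization. Core histones went to 12 and 10 and to 9 and 9 in the same order, and starch synthesis to 5 and 5 with either. Starch breakdown went to 8 and 7 with median-ratio scaling. Quantile normalization gave 7 and 7 for sucrose metabolism, 17 and 17 for lignin and xylem, 6 and 7 for abscisic acid, 3 and 6 for expansins, 5 and 9 for cellulose synthesis and 0 and 2 for glycoalkaloid synthesis. Over all tested genes the median log2 fold change at 28 d against 20 d was -0.1, and camera's direction is relative to the other genes. Camera pointed upward while the median was negative for core histones (median -0.02, mean -0.19), pectin modification (-0.12 and 0.04), starch synthesis (-0.06 and -0.05), starch breakdown (-0.1 and -0.06), sucrose metabolism (-0.27 and -0.09), gibberellin (-0.09 and -0.07), lignin and xylem (-0.1 and -0.08) and the m6A machinery (-0.05 and 0.06). Of these medians, median-ratio scaling turned core histones to 0.06 and starch synthesis to 0.02, and quantile normalization turned core histones to 0.04, starch breakdown to 0.01, gibberellin to 0.04 and lignin and xylem to 0.06. Adjusted over the list alone, the counts of higher and lower members became 10 and 57 for the photosynthetic light reactions, 3 and 14 for the Calvin cycle, 1 and 29 for cell division, 20 and 35 for pectin modification, 5 and 16 for cellulose synthesis and 7 and 14 for aquaporins. They became 5 and 5 for starch synthesis, 7 and 8 for starch breakdown, 11 and 4 for carotenoid synthesis, 12 and 30 for auxin response and 3 and 16 for cytokinin. Likewise they became 2 and 11 for flavonoid synthesis, 15 and 30 for cuticle formation, 16 and 22 for lignin and xylem, 24 and 6 for heat shock proteins, 11 and 41 for pathogenesis and 5 and 160 for ribosomal proteins, and were the same for the other lists.

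**Figure D3:**
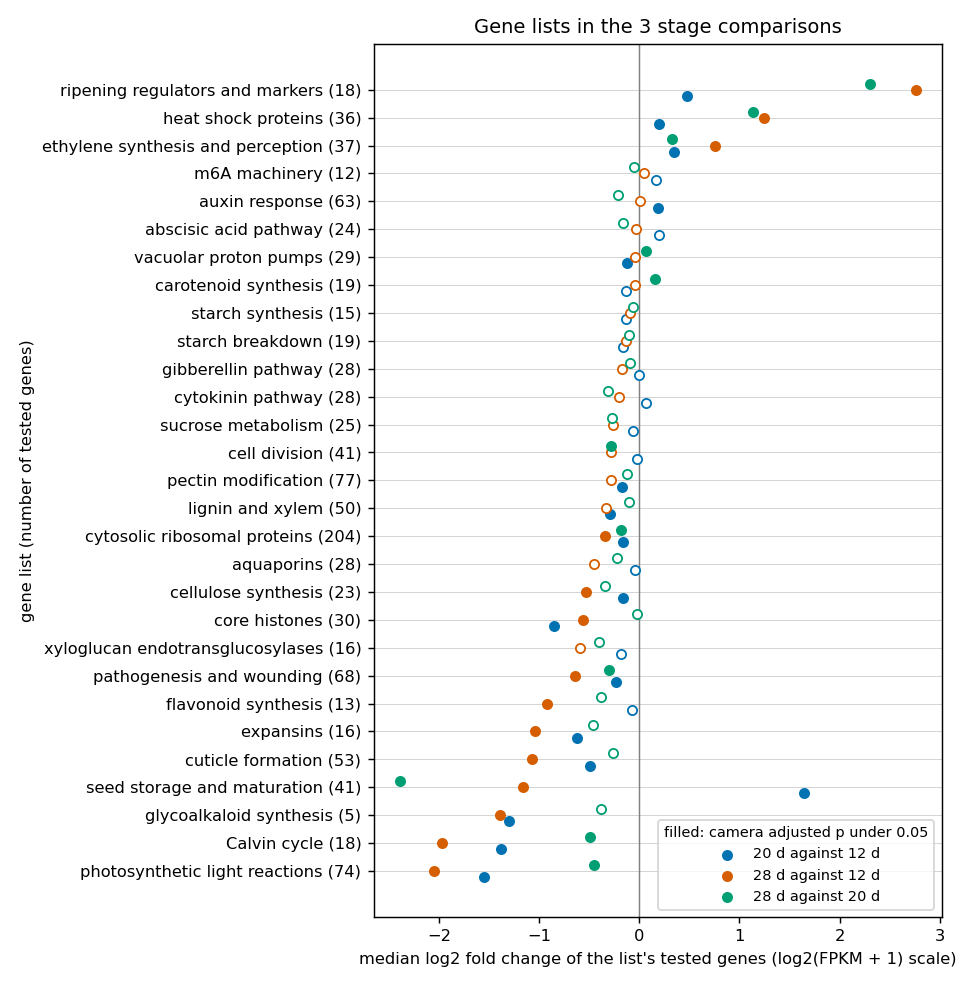
Median log2 fold change (log2(FPKM + 1) scale) of each gene list in the 3 comparisons, with the number of tested genes in brackets; filled points passed camera with an adjusted p under 0.05 at the preset correlation. Seed storage and maturation lies at 1.64 for 20 d against 12 d and at -2.39 for 28 d against 20 d, and ripening regulators and markers at 2.76 for 28 d against 12 d.

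Many of the changes against 12 d were shared by the later stages. In both comparisons 4669 genes were higher, among them polygalacturonase-2 (Solyc10g080210.2) and 1-aminocyclopropane-1-carboxylate oxidase 1 (Solyc07g049530.3), and 4626 were lower, among them ribulose bisphosphate carboxylase small chain 1 (Solyc02g063150.3). Independent lists of these sizes would share 2008 higher and 2009 lower genes. In 20 simulations of unchanged groups against shared 12 d libraries, limma called 0 genes in both. Where no gene is changed limma calls next to none, so that 0 cannot tell how much of the overlap comes from the shared libraries. The covariance of the log2 fold changes was 0.399, against 0.00278 simulated with no effect, which leaves 0.396. Across genes Pearson's r was 0.792, against 0.499 simulated. With no effect the shared reference alone sets that r, whatever the size of the noise, so it gives no scale for 0.792. The 2 libraries of 12 d were not split, since each part would hold 1, and part of the excess may come from the shared libraries. In opposite directions, 408 genes were higher at 20 d and lower at 28 d, and 143 were lower and then higher. At 2-fold or more, 135 genes were higher at 20 d than at 12 d and then lower at 28 d than at 20 d, 24 of them in the seed list. The opposite course, lower at 20 d and then higher at 28 d than at 20 d, held for 14 genes.

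Some genes differed widely between the libraries of a stage, and those named for it were chosen after their values were seen. Probable polyribonucleotide nucleotidyltransferase 1 is listed under neighbouring IDs, and in 12 d libraries Solyc08g066120.3 had 21.3 and 0 FPKM while Solyc08g066140.3 had 0 and 25. Glucan endo-1,3-beta-glucosidase B (Solyc01g059980.3) had 0.0293 and 126 FPKM in the 28 d libraries, while its neighbour of the same description, Solyc01g059965.1, had 111 and 11.4. Among genes reaching 3 FPKM, 54 at 12 d, 47 at 20 d and 42 at 28 d were more than 2-fold apart on the log2(FPKM + 1) scale, 104 genes in all, of which 86 were tested and 22 were called in some comparison.

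**Figure D4:**
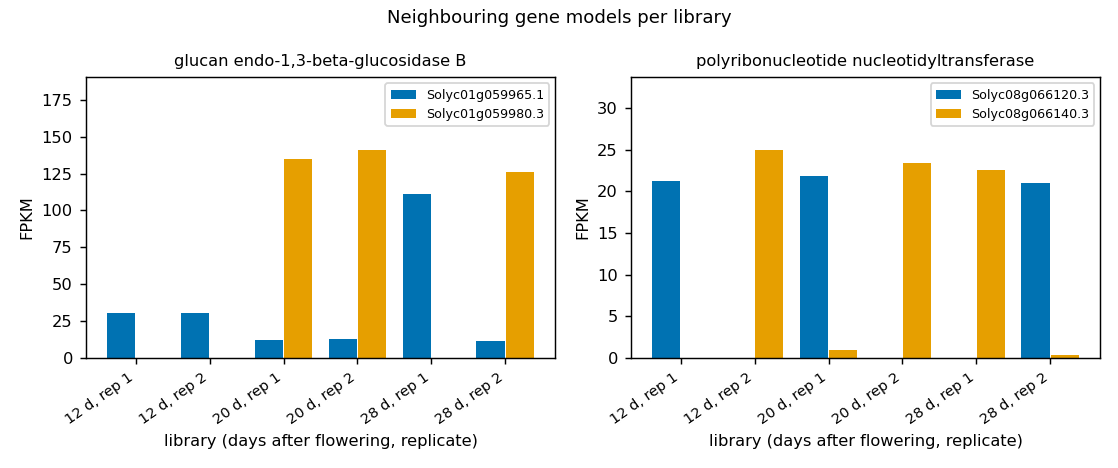
FPKM of a pair of neighbouring gene models in each panel, with 1 bar per gene and library. Solyc01g059965.1 is at 111 FPKM in the 28 d library where Solyc01g059980.3 is at 0.0293, and at 11.4 in the other, where Solyc01g059980.3 is at 126.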

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

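All tests of explanations in this part were chosen only after the results were seen. The results given here moved in opposite directions between 12 d and 20 d and between 20 d and 28 d. Both steps passed limma's test for a gene, or camera at the preset correlation for a list. They also differed from 12 d in opposite directions at 20 d and 28 d, and both of those differences passed too. Results with opposite steps but without that are not listed. Among these are protein LE25 (log2 fold change 3.84, then -3.47), MT-A70-like (0.16, then -0.22), V-type ATPase subunit G 1-like (-0.74, then 0.25) and the vacuolar proton pump list (median -0.12, then 0.07).

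For the seed storage and maturation list, the fall at 28 d against 12 d passed camera at the preset correlation (adjusted p = 7.5e-05). It did not pass with an estimated correlation (adjusted p = 0.072). The list peaked at 20 d, with a median log2 fold change of -2.39 at 28 d against 20 d after 1.64 at 20 d against 12 d. Median-ratio scaling left the later value at -2.35 and quantile normalization at -2.22, which argues against library scaling as its whole cause. A different share of seed tissue alone would move all seed transcripts by 1 factor, yet among 16 members called higher at 20 d, at 10 FPKM or more there, that fell at least 20-fold by 28 d (also 16 without asking for a call), the 20 d over 12 d folds ran from 1.84 to 10.2, a ratio of 5.52. That set was narrowed after 19 members had given 8.96, with a smallest fold of 1.13, and without the member of smallest fold (Solyc07g064210.2) the other 15 ran from 3.99 to 10.2, a ratio of 2.55. These folds cover only the step from 12 d to 20 d. From 20 d to 28 d the 16 members fell 24- to 156-fold, and a changed share at that step was not tested. A changed share together with changing expression within the seed may be involved and stays open, as does a biological difference between stages, which was not tested.

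The summed FPKM of those 16 members went from 1019 at 12 d to 6905 at 20 d and 89.3 at 28 d. Of the list's 41 tested members, 9 had 10 FPKM or more at every stage, and 0 belong to another list. At 28 d against 20 d the log2 fold change was -6.73 for vicilin (Solyc09g082340.2), -6.63 for 11S globulin seed storage protein 2-like (Solyc09g072560.3), -6.58 for 11S globulin subunit beta (Solyc09g090150.3), -6.49 for 12S seed storage protein CRA1-like (Solyc09g025210.3), -5.72 for legumin B-like (Solyc03g005580.2) and -5.47 for oleosin 5-like (Solyc12g010920.2). For the pair described as 2S sulfur-rich seed storage protein 2-like, which lie next to each other in ID order, it was -5.85 (Solyc08g080480.3) and -5.76 (Solyc08g080490.3), and reads shared between them were not examined.

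Other genes of this kind are given as values. The lipid-transfer proteins Solyc01g090360.3 and Solyc01g090350.3 had log2 fold changes of -4.56 and -3.71 at 28 d against 20 d, after 3.44 and 3.2 at 20 d. Both are in the cuticle formation list, so a rise and fall of this kind also occurred outside the seed list. Proline-rich protein 4-like (Solyc10g054900.2, chosen after its values were seen) had -3.35 after 0.85. Two-component response regulator ARR5 (Solyc05g006420.3) had -0.5 after 0.32, and flavonol synthase/flavanone 3-hydroxylase (Solyc11g013110.2) had 0.42 after -0.3. Heat shock cognate 70 kDa protein 2-like (Solyc09g010630.3) had -0.29 after 0.13, the earlier call being lost with quantile normalization (adjusted p = 0.7). 15-cis-zeta-carotene isomerase (Solyc12g098710.2) had 1.56 after -0.13, the earlier call being lost without the second 12 d library (adjusted p = 0.1), without the first 20 d library (0.099) and with a constant prior variance (0.051). Pyruvate dehydrogenase E1 component subunit alpha-3 (Solyc12g009400.2, chosen after its values were seen) had 0.58 after -0.15, the earlier call being lost without the second 12 d library (adjusted p = 0.17), the first (0.11) or second 20 d library (0.095), with no filter (0.06) and with a constant prior variance (0.074).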

How the results depend on the processing

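The counts of genes changed 2-fold or more were followed through the alternatives only after the data were seen; the other alternatives here were planned. Gene counts stayed within 1.5 times their value except where the threshold itself changed or 2-fold changes were counted. Adding a 2-fold threshold left 1376 genes at 20 d against 12 d, 2816 at 28 d against 12 d and 947 at 28 d against 20 d, by construction. A pseudocount of 5 lowered those 3 counts to 621, 1430 and 399, and a pseudocount of 0.1 raised the last to 1673, since the pseudocount shrinks folds of low values by construction. Of 87 list tests, 42 passed at the preset correlation and 9 with an estimated correlation, which also rests on the 3 residual degrees of freedom. With median-ratio scaling 46 passed. Each of the 42 passed in every fit that left out a library. Fits that leave 1 library in a stage assume that it varies like those of the other stages, and the spread between libraries was larger at low FPKM.

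The replicate block changed counts little. With the block 11199 genes were called at 20 d against 12 d, 13173 at 28 d against 12 d, 9650 at 28 d against 20 d and 14324 over the 3 stages, with 9068 in the same direction at both later stages and 42 list tests passed. Library differences correlated between stages at -0.096, -0.066 and 0.024 over 3306 genes of 30 FPKM or more, so the replicate numbers give no sign of pairing. Among the genes named, the block ended the call of Solyc08g082180.3 at 20 d against 12 d (adjusted p = 0.059) and of Solyc02g090890.3 at 28 d against 20 d (0.051), and no other call of a named gene or list.

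Over 338 gene-comparison pairs, leaving out a library lost 40 calls in 14 pairs, gained 2 and reversed 10 values. Other settings lost 26 calls with the direction kept, gained 6 and reversed or set to 0 another 7 values. Some of those 7 were lost calls too. They were Solyc09g065755.1, Solyc07g006560.3 and Solyc02g036350.3 at 28 d against 20 d, and Solyc04g071610.3 at 28 d against both other stages. The cause was not tested unless given. At 20 d against 12 d, reversed log2 fold changes were -0.033 with median-ratio scaling, -0.07 without the first 12 d library and -0.02 without the first 20 d library for Solyc03g112520.3 (-0.07 to 0.11 over the libraries left out), 0.039 and 0.022 without the first 12 d or second 20 d library for Solyc01g057570.3 (-0.07 to 0.039), and 0.06 without the second 20 d library for Solyc09g074920.3 (-0.12 to 0.06). At 28 d against 12 d they were -0.0044 and -0.0062 without the first 12 d or second 28 d library for Solyc05g056210.3 (-0.0062 to 0.034) and 0.0025 without the second 12 d library for Solyc03g112520.3 (-0.18 to 0.0025). At 28 d against 20 d they were -0.07 and -0.1 without the second 20 d or first 28 d library for Solyc12g096230.2 (-0.1 to 0.1), 0.021 with quantile normalization for Solyc04g015080.3, 0.0093 with median-ratio scaling for Solyc09g065755.1, and 0.025 with quantile normalization for Solyc07g006560.3. Quantile normalization gives genes of equal rank equal values by construction, and so set to 0 Solyc02g036350.3 at 28 d against 20 d and ASR1 (Solyc04g071610.3), chosen after its values were seen and the highest gene of each library, at 28 d against both other stages.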

Other observations

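The tests of explanations in this part, the pathway tests and the choice of genes named in its first paragraphs all came after the results were seen.

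Several abundant transcripts outside the gene lists rose at each step. UDP-glycosyltransferase 73C3-like (Solyc10g085880.1) went from 112 ± 0.85 FPKM at 12 d to 341 ± 15 at 20 d and 1755 ± 61.4 at 28 d, and linoleate 9S-lipoxygenase B (Solyc01g099190.3), which oxidizes fatty acids, from 77.8 ± 0.0558 to 253 ± 4.67 and 872 ± 3.08. BAG family molecular chaperone regulator 6 (Solyc01g095320.3) went from 111 ± 3.27 to 310 ± 3.86 and 1063 ± 6.78 FPKM, temperature-induced lipocalin (Solyc12g010320.2) from 109 ± 4.26 to 215 ± 4.83 and 625 ± 2.07, and heat stress transcription factor A-6b-like (Solyc06g053960.3) from 66.6 ± 0.467 to 143 ± 3.39 and 288 ± 1.19. Protein NP24 (Solyc08g080640.2) rose 11-fold from 12 d to 28 d. All 6 were called by limma at both steps (n = 2 libraries per stage).

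Others fell at each step. Induced stolen tip protein TUB8-like (Solyc05g054090.3) went from 5032 ± 34.1 FPKM at 12 d to 1264 ± 38.5 at 20 d and 275 ± 0.145 at 28 d, pollen proteins Ole e I-like (Solyc06g074260.3) from 3008 ± 35.6 to 1267 ± 6.01 and 374 ± 3.19, and transcription factor MYB1R1 (Solyc03g113620.3) from 612 ± 9.43 to 297 ± 2.62 and 113 ± 1.2. Isopropylmalate synthase (Solyc08g014130.3), of leucine synthesis, had 43.7 ± 0.392 and 42.9 ± 0.726 FPKM at 12 d and 20 d and rose to 137 ± 1.74 at 28 d. Of 127 KEGG pathways, 11 passed camera at 20 d against 12 d, 4 at 28 d against 12 d and 8 at 28 d against 20 d, with 0 past an adjusted p of 0.05 with an estimated correlation (lowest 0.24, 0.43 and 0.38). As for the lists, that setting is limited by the 3 residual degrees of freedom. Photosynthesis antenna proteins had 35 of 36 lower and 1 higher at 20 d (adjusted p = 1.9e-18, and adjusted p = 0.25 with an estimated correlation), among them chlorophyll a/b-binding protein Cab-1B (Solyc02g071020.3), lower 4.05-fold. The citrate cycle at 28 d against 20 d had 28 of 69 higher and 12 lower (median log2 fold change 0.05, adjusted p = 0.0004, and adjusted p = 0.38 with an estimated correlation), and isocitrate dehydrogenase [NADP]-like (Solyc11g011930.2) rose 1.57-fold. The pathways were not tested under other scalings.

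Of the 104 genes whose libraries of a stage lay more than 2-fold apart, 30 (28.8%) had a gene within 3 places in ID order that moved the other way by more than 2-fold, and 2 had one that moved the same way. In 100 windows of as many places, 51 to 350 places away, a mean of 1.14 and at most 6 of the 104 genes had an opposite gene; an earlier comparison with places 51 to 56 had given 0. That is consistent with reads being divided differently between neighbouring gene models, as a hypothesis for those 30 genes. For the other genes no explanation was tested, and values of single genes in such pairs may reflect the division more than the transcript.

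At 28 d against 20 d more genes were called lower than higher, 31.1% of calls being higher. Median-ratio scaling gave 46.3%, but it brings each comparison near an even split by construction (47.2% at 20 d against 12 d and 46.6% at 28 d against 12 d), so for all calls the scaling of the libraries and a wide lowering of expression cannot be told apart. Among calls of 2-fold or more, 39.4% were higher as deposited and 46.2% with median-ratio scaling, while the same scaling left 20 d against 12 d at 32.8% and 28 d against 12 d at 34.7%. Quantile normalization gave 52.5%, and without scaling the share was 28.6% with a pseudocount of 0.1 and 54.1% with 5, so the scaling may account for part of the 2-fold excess, as may the weight given to low values. A biological difference between the stages stays open and was not tested.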
